A study of Mus musculus with 62 samples.

How the data were processed

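Cerebellum RNA of female mice was sequenced in 62 libraries. The animals had been injected with cachectic melanoma cells (CAC), with non-cachectic melanoma cells (NCAC), or had a mock injection, and tissue was taken 2, 4, 6 or 8 weeks (wk) after injection. Each of the 12 groups held 5 libraries, except CAC at 8 wk with 7. Groups and replicate numbers were taken from the sample descriptions, with which the sample titles agreed. The treatment field of the labels names cachectic cells for every sample and was not used. The labels disagree on the strain: the sample fields name C57BL6/J, whereas the series design names NCI Ath/nude mice. The strain was therefore left open. The extraction protocol also refers to a time point after injection of LLC cells, which disagrees with the melanoma design and was not used. Per the labels' protocols, tissue was homogenized in Trizol and libraries were made with a stranded mRNA kit. Each replicate was described as a biological replicate, though no label ties a library to a named animal.

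The authors deposited 1 table of TPM values (transcripts per 1e+06 transcripts) per gene symbol for all libraries. Per the submitters' processing notes the genome build was mm10. The aligner, the quantification tool and the gene annotation are not given in the sources used here. TPM divides each gene's signal by its length and scales every library to the same total of 1e+06, so the table keeps no sequencing depth. The depth per library is unknown, and no counting interval or detection floor is given. A gene that takes more of the total lowers the TPM of the others by construction. Of 47643 symbols in the table, 23124 were at 0 in every library. Symbols were matched to GENCODE mouse release M21, which uses the same build, for coordinates: 45134 symbols were found, among them 13929 of the tested ones. Genes with near-identical copies, among them Serpina3h, Ly6c1 and the immunoglobulin genes, are uncertain, since it is not stated how reads shared between copies were assigned.

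Levels were analysed as log2(TPM + 1), for the 14399 symbols with a mean TPM of at least 1 over all libraries. Fold changes are on this scale, which understates the change of genes with low TPM. All 12 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, and eBayes with an intensity trend), with 50 residual degrees of freedom and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 14 comparisons were the 3 pairings of treatments in each of the 4 weeks, the change of the CAC against mock difference from 2 to 8 wk, and mock at 8 wk against mock at 2 wk. Errors of fold changes are standard errors (SE), and errors of TPM are standard deviations (SD).

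Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation, with adjustment over the lists of a comparison. The 34 lists covered signalling responses, metabolism, organelles, cell types of the cerebellum, and cells or tissue that dissection could carry over. They held 597 different genes, of which 595 were in the table and 520 were tested. Counts of list members below are of tested genes. Some genes stand in more than 1 list, such as Lcn2 in the glucocorticoid and inflammation lists. The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the largest and the 10 with the smallest log2 fold change past the threshold in comparisons of CAC, and 5 and 5 in the others. It left out clone and pseudogene names, and added up to 4 members of each list with the smallest p. Some genes that the rule takes are not reported here by name and stay in the counts.

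The fit was tested on simulated data made from these libraries. For CAC against mock at 8 wk, 31 of 50 genes changed by 1.25-fold were recovered, 43 of 50 at 1.5-fold, 47 at 2-fold and 49 at 4-fold, with 7 false calls among 14399 genes. For NCAC against mock at 8 wk the numbers were 31, 43, 44 and 50 of 50, with 11 false calls. The list test recovered the 1 list that had been shifted and called 0 of the 33 others. The simulated noise was drawn for each gene on its own, without correlation between genes. In the real libraries the estimated correlation was 0.869 within the choroid plexus list and 0.684 within the glucocorticoid list. The simulation therefore cannot show how many false calls, of genes or of lists with the preset correlation, arise among correlated genes.

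The alternatives were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, sample weights, a replicate block, a choroid plexus covariate, a fit on the compared groups alone, a limit of 1.5-fold, and leaving out each replicate in turn. Alternatives added after seeing the data removed the mitochondrially encoded genes, removed 39 genes whose libraries fell into separate levels, or left out CAC replicate 3 and mock replicate 5 of 8 wk together. The simulated share of genes with the same sign in an earlier week was also added after seeing the data. No pair of libraries held identical values, and the highest correlation of any pair was 0.9949 on the log2 scale. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.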

Results

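The series followed the cerebellum over the development of cachexia, the wasting that can accompany a tumour. It comprised 62 RNA-seq libraries from mice given a melanoma that causes cachexia (CAC), a melanoma that does not (NCAC), or a mock injection. Tissue was collected 2, 4, 6 and 8 wk after injection, with 5 libraries per group and 7 for CAC at 8 wk. Values were TPM, so the depth of each library is unknown. Mitochondrially encoded transcripts took between 19 ± 1.31% (SD, n = 7) of the TPM in CAC at 8 wk and 20.9 ± 1.19% (SD, n = 5) in mock at 8 wk. Ttr, an abundant transcript of the choroid plexus, ranged from 4.34 to 6860 TPM over all libraries and varied widely within each week.

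The first question was whether the cerebellum of mice with cachectic melanoma differed from that of mock-injected mice at 8 wk. Lrg1, which encodes a secreted glycoprotein raised in inflammation, was at 16.8 ± 5.27 TPM (SD, n = 7) in CAC and 1.97 ± 0.473 (SD, n = 5) in mock, a log2 fold change of 2.52 ± 0.235 (SE; adjusted p = 8.86e-11). The lowest CAC library, at 6.57 TPM, lay above the highest mock library, at 2.8. Plin4, a lipid droplet coat protein, rose from 2.59 ± 1.79 to 25.5 ± 14.4 TPM, and Fkbp5, a co-chaperone of the glucocorticoid receptor, from 5.56 ± 1.38 to 28.6 ± 12.7. Fabp7, a fatty acid binding protein of astrocytes and Bergmann glia, fell from 103 ± 17.1 to 29.2 ± 22.2 TPM, a log2 fold change of -2.01 ± 0.344 (adjusted p = 3.8e-05). Opalin, a membrane protein of oligodendrocytes, fell from 14.3 ± 3.29 to 5.25 ± 2.78 TPM.

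**Figure D1:**
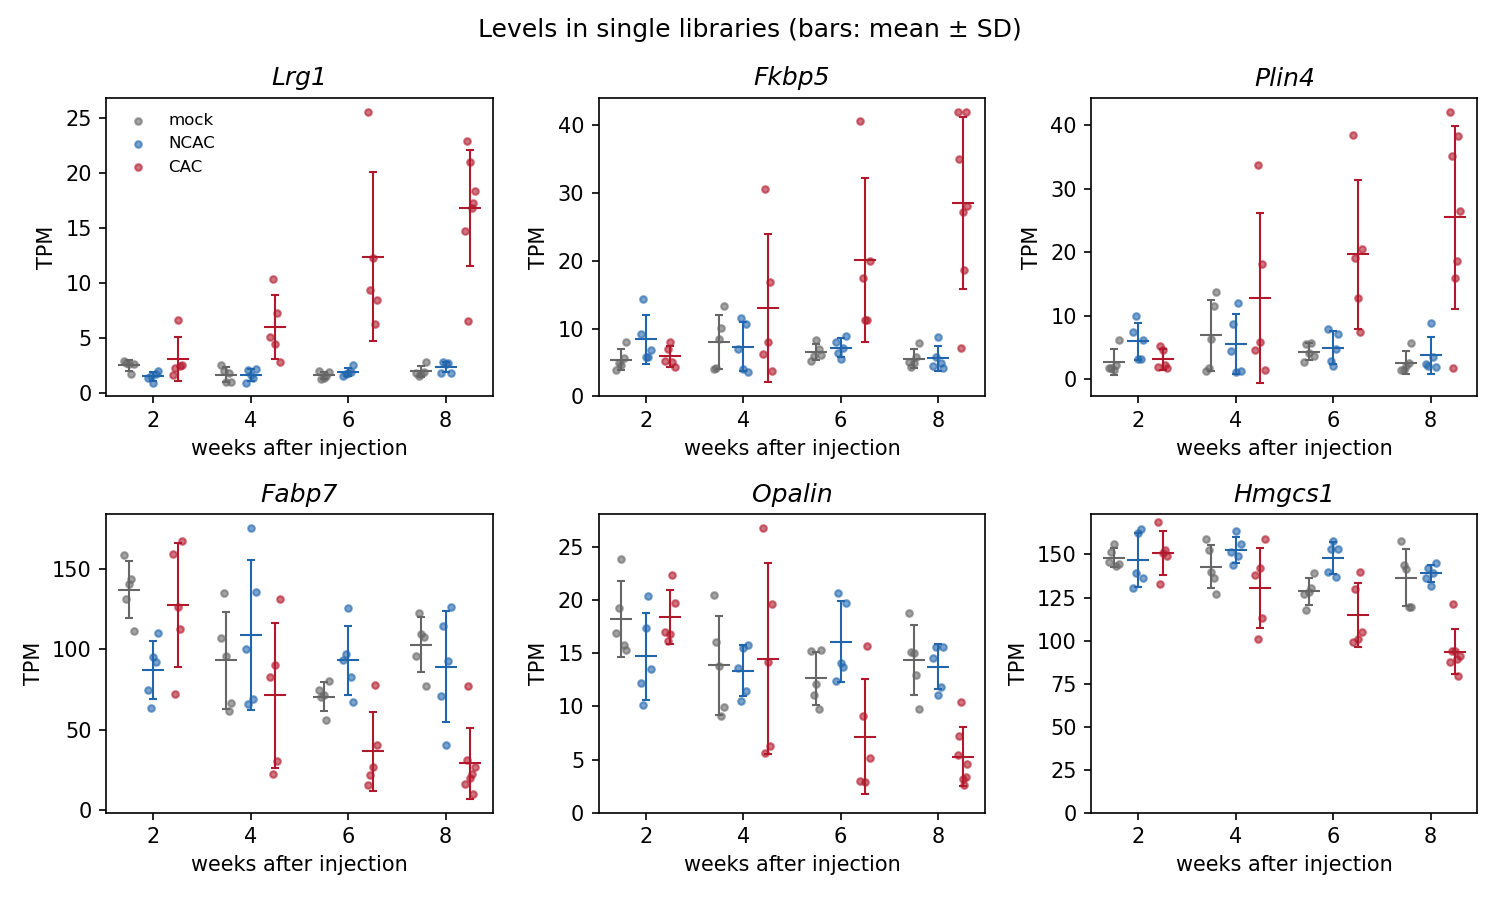
TPM (y axis) of 6 genes in every library by weeks after injection (x axis), for mock (grey), NCAC (blue) and CAC (red); points are libraries, horizontal marks are means and bars are ± SD. At 8 wk Lrg1 averaged 16.8 TPM in CAC against 1.97 in mock and 2.38 in NCAC, and Fabp7 averaged 29.2 TPM against 103 and 89.2.

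In limma, 2990 of 14399 genes passed the threshold at 8 wk, 1933 higher and 1057 lower in CAC, with a median size of 0.227 on the log2 scale. Of these, 241 differed by at least 1.5-fold, 161 higher and 80 lower. The share of calls that were higher, 64.6%, was 49.4% with median-of-ratios scaling and 47% with quantile normalization, so the direction split depends on the scaling. With mitochondrially encoded genes removed, a setting chosen after seeing the data, 1282 genes were higher and 1791 lower. A fit on these 2 groups alone called 1648 genes.

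Other large rises were those of Etnppl (log2 fold change 2.55), a phosphoethanolamine lyase of astrocytes, the kinase Map3k6 (2.20), the sulfotransferase Sult1a1 (2.13), Lcn2 (2.01), an acute-phase protein that binds siderophores, Ch25h (1.92), which makes an oxysterol, and the transcription factors Zbtb16 (1.89) and Hif3a (1.78). Lcn2 was at 5.54 ± 3.58 TPM in CAC and 0.474 ± 0.316 in mock, and Ch25h at 4.72 ± 1.53 and 0.485 ± 0.313. The largest falls included the matrix protein Tnc (-1.72), Sost (-1.60), which encodes sclerostin, and Gkn3 (-1.58). The immunoglobulin genes Igkc (-2.37), Ighg2c (-1.79), Iglv1 (-1.69) and Iglc1 (-1.55) and the MHC class II gene H2-Eb1 (-1.52) were also called lower, but none of these 5 was called without mock replicate 5, in which Igkc stood at 426 TPM (adjusted p without it: Igkc 0.134, Ighg2c 0.231, Iglv1 0.0572, Iglc1 0.175 and H2-Eb1 0.128). The call of Zbtb16 was lost with a replicate block (adjusted p = 0.0593), which takes CAC replicates 6 and 7 out of this comparison.

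All 20 measured members of the glucocorticoid list rose at 8 wk, over all genes and adjusted over the list alone, with a median log2 fold change of 1.54. Besides Fkbp5 and Lcn2 they included the metallothioneins Mt1 (1.52) and Mt2 (1.72) and the stress-inducible Ddit4 (0.81). The list passed with the preset correlation (adjusted p = 1.66e-19) but not with an estimated one (adjusted p = 0.141). CAC replicate 3 stood apart, with a list mean of 4.955 on the log2 scale against 5.7 to 6.294 in the other 6 CAC libraries and 4.103 to 4.839 in mock. Its Plin4, at 1.703 TPM, and its Fkbp5, at 7.143, lay within the mock ranges of 1.352 to 5.666 and 4.258 to 7.825 TPM. Of 23 members of the acute inflammation list 10 were tested. Of these, 7 rose over all genes and 7 adjusted over the list alone, among them Lrg1, Ch25h and Socs3 (0.82). Lcn2 and Ch25h averaged 0.474 and 0.485 TPM in mock, so the filter over all libraries can favour members that are high in CAC. This list had a median of 0.834 and passed both ways (adjusted p = 3.55e-09, and adjusted p = 0.0111 with an estimated correlation). It lost its call with a mean TPM of at least 5 (adjusted p = 0.528), a filter under which Lrg1 and Lcn2 are no longer tested. Of 17 clock genes, 8 rose over all genes and 10 adjusted over the list alone, among them Bhlhe40 (0.57), Cry2 (0.32), Per3 (0.45) and Tef (0.45), with an adjusted p of 0.00302 and an adjusted p of 0.294 with an estimated correlation.

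The lists of myelin, precursor and cholesterol synthesis genes were lower in CAC at 8 wk with the preset correlation only. Of 16 oligodendrocyte and myelin genes, 11 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone. Mag fell by 0.50 on the log2 scale and Ugt8a, which makes galactosylceramide, by 0.93. Of 10 precursor genes 4 fell, also adjusted over the list alone, with Bcas1 at -0.51, Enpp6 at -0.64, Gpr17 at -0.89 and C1ql1 at -0.59. Of 23 cholesterol synthesis genes 13 fell and 0 rose, also adjusted over the list alone (limma). Hmgcs1, an early enzyme of the pathway, was at 93.6 ± 13 TPM in CAC and 136 ± 16.7 in mock, and Idi1 had a log2 fold change of -0.51. The adjusted p-values were 9.56e-07 for myelin, 0.00132 for precursors and 3.55e-09 for cholesterol. With an estimated correlation none of these passed (adjusted p = 0.214, 0.197 and 0.214).

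Microglial, interferon and heat shock genes were lower as lists at 8 wk, with the preset correlation only. Of 15 microglial genes 5 fell, 9 adjusted over the list alone, with Sall1 at -0.56, Aif1 at -0.72 and P2ry12 at -0.39. Mock replicates 5 and 3 had microglial list means of 4.641 and 4.362 on the log2 scale, against 3.793 to 4.108 in the other mock libraries and 3.595 to 3.997 in CAC. Without mock replicate 5 the list median went from -0.341 to -0.167 (adjusted p = 0.00247). Of 20 interferon response genes 4 fell and 1 rose, also adjusted over the list alone, with Gbp2 at -0.83, Gbp3 at -0.94 and B2m at -0.66; this list lost its call with a mean TPM of at least 5 (median -0.254; adjusted p = 0.0965), and its median went from -0.484 to -0.288 without mock replicate 3 (adjusted p = 0.00337). Of 17 heat shock genes 7 fell, 8 adjusted over the list alone, with Hspd1 at -0.19. Of 13 mitochondrially encoded genes 8 fell, 10 adjusted over the list alone, led by mt-Nd2 at -0.32; under quantile normalization the list median was 0 (adjusted p = 0.889) and mt-Nd4, mt-Nd4l and mt-Cytb changed sign. Of 59 cytosolic ribosomal genes 20 rose, 27 adjusted over the list alone, with Rps27a at 0.20. Adjusted p-values with the preset correlation were 3.97e-06 for microglia, 1.38e-04 for interferon, 1.26e-04 for heat shock, 3.99e-06 for mitochondrial and 1.87e-05 for ribosomal genes. With an estimated correlation the adjusted p-values were 0.294, 0.401, 0.401, 0.294 and 0.422.

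Nuclear genes of oxidative phosphorylation (5 lower and 1 higher of 38), presynaptic genes (3 lower and 1 higher of 18) and lymphocyte genes (2 lower of 3) also passed with the preset correlation (adjusted p = 0.0191, 0.0191 and 0.0323), not with an estimated one (adjusted p = 0.531, 0.315 and 0.29). The lymphocyte list rested on Igkc and Ighm, and without mock replicate 5 its median went from -0.915 to -0.142 (adjusted p = 0.297). Its call was also lost without CAC replicate 3 or 5 (adjusted p = 0.0635 or 0.0676), with a mean TPM of at least 5 (0.0524), median-of-ratios scaling (0.0677), quantile normalization (0.0846) or sample weights (0.116), without mitochondrially encoded genes (0.0947) and in a fit on the 2 groups alone (0.0841). The oxidative phosphorylation list had an adjusted p of 0.169 without mock replicate 1. Lists of Purkinje, granule, inhibitory, astrocyte and Bergmann, endothelial, mural, meningeal, choroid plexus, red blood cell, neutrophil, melanocytic, forebrain and brainstem genes did not pass. Neither did those of immediate early, fasting, integrated stress, atrophy and autophagy, proteasome, basement membrane and proliferation genes. Their adjusted p-values lay between 0.158 and 0.993. Single members of these lists that changed included the transcription factor Foxo1 (0.89), the fasting-induced kinase Pdk4 (1.32), the matrix gene Sparc (0.75), the endothelial genes Ly6c1 (0.83) and Kdr (-0.69), and the water channel Aqp4 (-0.57).

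At 6 wk the same comparison was led by Lrg1, at 12.4 ± 7.69 TPM in CAC and 1.62 ± 0.317 in mock (SD, n = 5 each; log2 fold change 2.21, adjusted p = 1.22e-07). Etnppl was at 50.4 ± 19 TPM against 11.4 ± 2.91, and Phyhd1, a dioxygenase, at 35.2 ± 11.8 against 11.7 ± 3.28. Gkn3 was lower, at 3.18 ± 2.55 against 10.2 ± 2.58 TPM. Other large rises were those of Map3k6 (1.64), Sult1a1 (1.49), Tmem252 (1.39), Ch25h (1.38), Fkbp5 (1.35), Lcn2 (1.24) and the cell cycle inhibitor Cdkn1a (1.16). Tnc (-1.33), Sost (-1.08), Dhrs2 (-0.75), Cacna1e (-0.64), Ddah2 (-0.53), Pm20d1 (-0.51), Mfge8 (-0.50), Spef1 (-0.50) and Car15 (-0.46) fell.

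In limma 248 genes passed at 6 wk, 203 higher and 45 lower, of which 58 differed by at least 1.5-fold. The higher share of 81.9% was 57.6% with median-of-ratios scaling and 48% with quantile normalization, and without mitochondrially encoded genes 122 genes were higher and 82 lower. These calls depended on the spread shared by all 12 groups: a limma fit on the 2 groups alone, with 8 residual degrees of freedom, called 0 genes, with 2057 at an unadjusted p under 0.05, and Lrg1 had an adjusted p of 0.0644. The count also depended on single libraries, with 20 without CAC replicate 1, 96 without CAC replicate 2, 527 without CAC replicate 4, and 104, 68, 136 and 96 without mock replicates 2, 3, 4 and 5. Of 20 glucocorticoid genes 7 rose, 13 adjusted over the list alone (median 0.836; adjusted p = 2.67e-11, and adjusted p = 0.424 with an estimated correlation). Of 10 inflammation genes 6 rose, 8 adjusted over the list alone (adjusted p = 1.95e-11, and adjusted p = 0.00189 with an estimated correlation), but the list lost its call with a mean TPM of at least 5 (median 0.0818; adjusted p = 0.32).

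At 4 wk 1 gene passed in CAC against mock. Lrg1 was at 6.01 ± 2.9 TPM in CAC, 1.68 ± 0.677 in mock and 1.66 ± 0.527 in NCAC (SD, n = 5 each), a log2 fold change of 1.32 ± 0.254 against mock (adjusted p = 0.0435) and 1.32 against NCAC (adjusted p = 0.0436). All 5 CAC libraries, from 2.81 TPM, lay above the mock and NCAC libraries, which reached 2.52 and 2.22. The call of Lrg1 against mock was lost in a fit on the 2 groups alone (adjusted p = 0.592), with a replicate block (0.0732), median-of-ratios scaling (0.0509), quantile normalization (0.0713), sample weights (0.0512) or the choroid plexus covariate (0.0791). It was also lost without CAC replicate 2 (0.784), 3 (0.0604) or 4 (0.39) or mock replicate 2 (0.0581), 3 (0.221), 4 (0.0922) or 5 (0.153), and the count was 4 and 2 without CAC replicates 1 and 5. Against NCAC it was lost in a fit on the 2 groups alone (adjusted p = 0.636), with a replicate block (0.146), median-of-ratios scaling (0.0531) or sample weights (0.0794). In that comparison 0 genes were called by limma without CAC replicate 1, 2, 3 or 4 or NCAC replicate 2, 3 or 5, and 10 and 9 without NCAC replicates 1 and 4. In all, 1149 genes were at an unadjusted p under 0.05 against mock and 1363 against NCAC, where 720 are expected by chance. At 2 wk limma called 0 genes in CAC against mock, with 697 at an unadjusted p under 0.05, and 0 in CAC against NCAC, with 987. Interferon genes were also lower as a list in CAC than in mock at 2 wk (median -0.497; adjusted p = 1.66e-12, and adjusted p = 0.444 with an estimated correlation), with 0 of 20 members called by limma and 7 at an unadjusted p under 0.05. Without mock replicate 5 of 2 wk that median was -0.195 (adjusted p = 1.71e-04). A change of this list difference between 2 and 8 wk did not pass the test (adjusted p = 0.853). Choroid plexus genes were lower with it (median -0.444; adjusted p = 0.00281, and adjusted p = 0.837 with an estimated correlation).

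**Figure D2:**
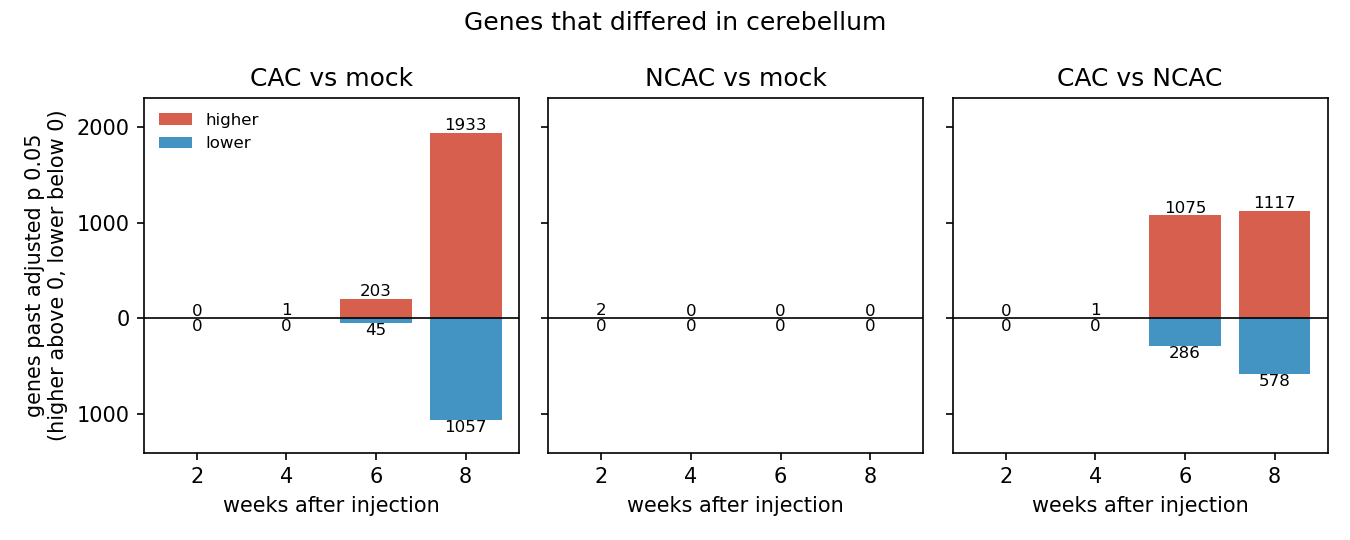
Number of genes past an adjusted p of 0.05 (y axis; higher above 0, lower below 0) by weeks after injection (x axis), for CAC against mock, NCAC against mock and CAC against NCAC. Counts in CAC against mock were 0, 1, 248 and 2990 from 2 to 8 wk, and at most 2 in NCAC against mock; the split into higher and lower depends on the scaling.

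The second question was whether a melanoma that does not cause cachexia changed the cerebellum. At 2 wk limma called 2 genes, both higher in NCAC. Mpc1, a mitochondrial pyruvate carrier, was at 222 ± 9.41 TPM in NCAC and 189 ± 4.13 in mock (SD, n = 5 each), a log2 fold change of 0.23 (adjusted p = 0.0259), and its call was lost with either scaling alternative, with a replicate block and in a fit on the 2 groups alone (adjusted p = 0.0746, 0.154, 0.213 and 0.0696), with the choroid plexus covariate (0.0797) and without mitochondrially encoded genes (0.0526). The count was 0 without NCAC replicate 3 or 5 or without mock replicate 1, 2 or 3, and 1 without NCAC replicate 1 or mock replicate 5, where Mpc1 was not called (adjusted p = 0.231 and 0.101). Limma called 0 genes in NCAC against mock at 4, 6 and 8 wk, with 306, 1202 and 1038 at an unadjusted p under 0.05. At 8 wk Lrg1 was at 2.38 ± 0.477 TPM in NCAC, Fkbp5 at 5.6 ± 1.88, Fabp7 at 89.2 ± 34.4 and Opalin at 13.7 ± 2.14 (SD, n = 5).

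No single gene passed in NCAC against mock at 8 wk, but 8 of 34 lists passed with the preset correlation. Among them 3 lists of immune genes were lower. These were microglia (median -0.376; 0 members called over all genes by limma and 11 of 15 lower adjusted over the list alone), lymphocyte (median -1.3; 2 of 3 adjusted over the list alone) and interferon genes (median -0.519; 4 of 20 adjusted over the list alone). With an estimated correlation the adjusted p was 0.0475 for microglia, 0.0431 for lymphocyte and 0.235 for interferon genes. Without mock replicate 5 the medians were -0.27, -0.501 and -0.368, and the adjusted p with the preset correlation was 7.42e-09, 0.0177 and 2.48e-06. The lymphocyte list had an adjusted p of 0.0558 in a fit on the 2 groups alone. At 2 wk, clock genes were higher in NCAC than in mock, with 12 of 17 higher and 2 lower adjusted over the list alone (median 0.378; adjusted p = 9.61e-10, and adjusted p = 0.0259 with an estimated correlation). Glucocorticoid genes were also higher as a list in NCAC at 2 wk (median 0.448; adjusted p = 2.67e-08, and adjusted p = 0.495 with an estimated correlation), with 0 of 20 members called by limma and 7 at an unadjusted p under 0.05. Genes of mural cells, which wrap the vessels, were lower as a list (median -0.155; 2 of 10 adjusted over the list alone; adjusted p = 1.3e-06, and adjusted p = 0.0495 with an estimated correlation). Markers of other tissue moved with them: choroid plexus (median -1.2), meningeal (-0.131) and basement membrane genes (-0.132) were lower as lists (adjusted p = 1.12e-12, 8.62e-04 and 2.67e-07), not with an estimated correlation (adjusted p = 0.173, 0.603 and 0.0509). NCAC replicates 1, 3 and 5 had choroid plexus list means of 1.109 to 1.233 on the log2 scale, against 2.518 to 4.507 in mock, and the lowest mural means, 3.827 to 3.929 against 4.078 to 4.205 in mock. The meningeal list lost its call without NCAC replicate 3 (adjusted p = 0.78), with sample weights (0.0962) and with the choroid plexus covariate (0.318), under which the mural list kept its call (median -0.158; adjusted p = 0.00108).

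**Figure D3:**
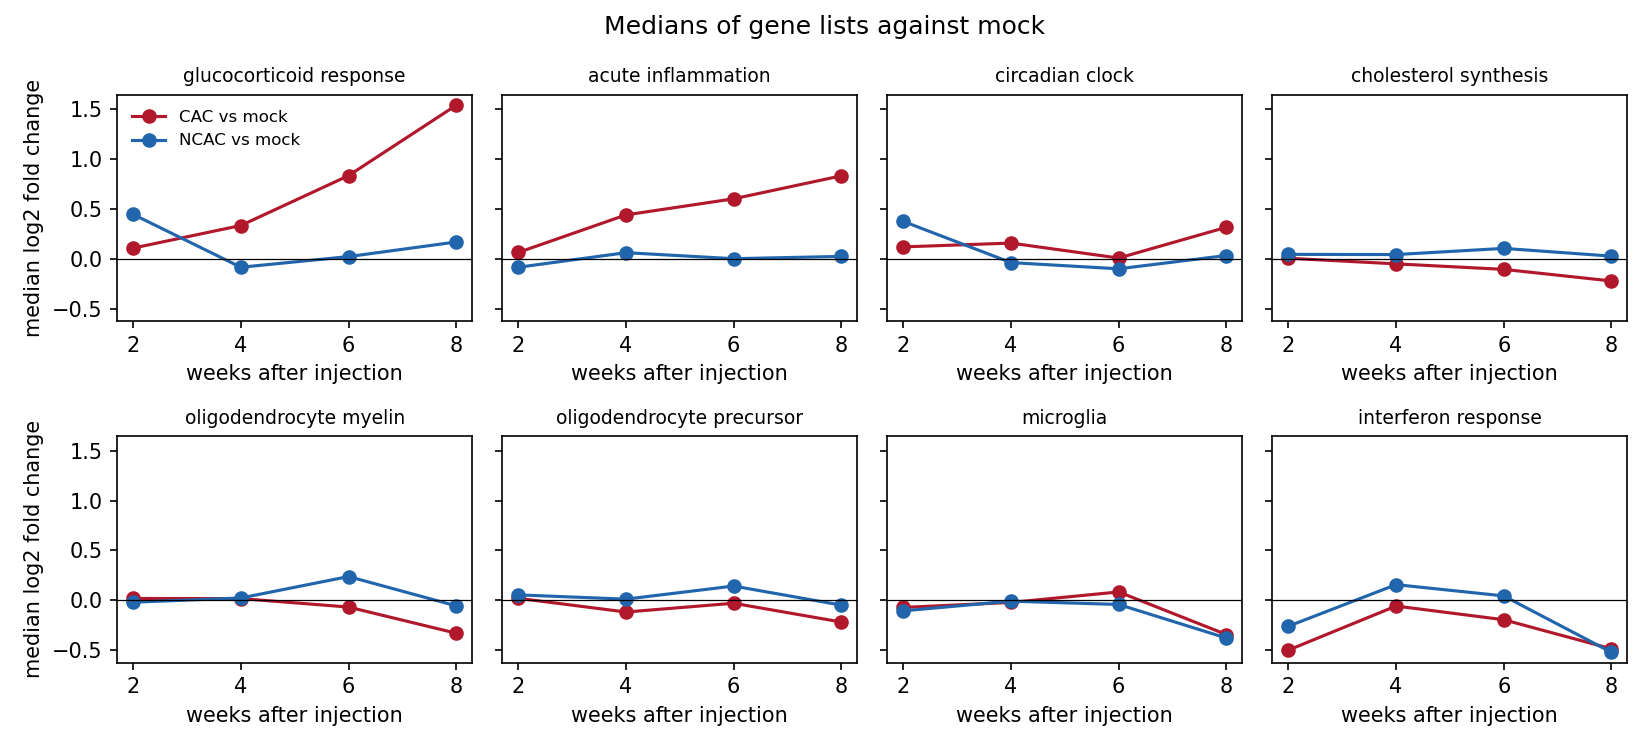
Median log2 fold change against mock (y axis) of 8 gene lists by weeks after injection (x axis), for CAC (red) and NCAC (blue). The glucocorticoid list had a median of 1.54 in CAC at 8 wk, and the microglial list was lower at 8 wk in CAC (-0.341) and in NCAC (-0.376). CAC and NCAC were set against the same mock libraries.

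The third comparison set the melanomas against each other. At 8 wk Lrg1 (log2 fold change 2.34), Plin4 (2.30), Etnppl (2.29), Fkbp5 (2.04), Map3k6 (2.02), Zbtb16 (2.01), Tmem252 (1.95), Sult1a1 (1.95), Serpina3h (1.87) and Lcn2 (1.85) were higher in CAC than in NCAC. Fabp7 (-1.73), Gkn3 (-1.68), Tnc (-1.39), Opalin (-1.34), Serpinb1a (-1.26), Cd70 (-1.19), Sost (-1.12), the neurotrophin Ntf3 (-1.04), the protease Klk6 (-1.04) and the collagen Col2a1 (-1.0) were lower. Limma called 1695 genes, 1117 higher and 578 lower, and 685 in a fit on these 2 groups alone. The higher share of 65.9% was 48.9% with median-of-ratios scaling and 45.7% with quantile normalization, and without mitochondrially encoded genes 735 genes were higher and 1065 lower. Without NCAC replicate 4 or 5 the count was 1127 or 1101.

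In the lists at 8 wk, 18 of 20 glucocorticoid genes were higher in CAC than in NCAC, 20 adjusted over the list alone (median 1.33; adjusted p = 1.18e-19, and adjusted p = 0.0911 with an estimated correlation). Of 10 inflammation genes 8 were higher, also adjusted over the list alone (adjusted p = 3.84e-13, and adjusted p = 8.73e-04 with an estimated correlation), but this list lost its call with a mean TPM of at least 5 (median 0.0826; adjusted p = 0.25). Of 23 cholesterol genes 12 were lower, 15 adjusted over the list alone, with Hmgcs1 at -0.58, Cyp51 at -0.55 and Sqle at -0.52. Of 16 myelin genes 8 were lower and 1 higher, 12 and 1 adjusted over the list alone. With an estimated correlation their adjusted p-values were 0.0911 and 0.16. Microglial genes did not pass between the melanomas (median 0.0476; adjusted p = 0.925). Of 4 tested forebrain genes, listed as markers of tissue that dissection could carry over, 3 were higher in CAC (Ppp1r1b 0.28, Neurod6 0.27 and Camk2a 0.18). This list had an adjusted p of 0.0188, and an adjusted p of 0.134 with an estimated correlation. It lost its call with no filter (adjusted p = 0.0635).

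At 6 wk, Etnppl was at 50.4 ± 19 TPM in CAC and 8.29 ± 3.58 in NCAC, and Lrg1 at 12.4 ± 7.69 and 1.92 ± 0.373 (SD, n = 5 each). Plin4 (1.74), Phyhd1 (1.5), Sh3rf3 (1.48), Sult1a1 (1.46), Map3k6 (1.46), Tmem252 (1.42), Ch25h (1.39) and Fkbp5 (1.22) were higher, and Fabp7 (-1.51), Gkn3 (-1.33), Tnc (-1.32), Opalin (-1.28), Col2a1 (-1.09), Sost (-0.97), Lypd2 (-0.96), Ugt8a (-0.77) and Dhrs2 (-0.73) lower. Limma called 1361 genes, 1075 higher and 286 lower, a higher share of 79% that was 42.7% with median-of-ratios scaling and 41.9% with quantile normalization; without mitochondrially encoded genes 556 were higher and 466 lower. A fit on the 2 groups alone called 348. The count was 247, 824 and 810 without CAC replicates 1, 3 and 5, and 663, 776 and 633 without NCAC replicates 2, 3 and 5. Of 16 myelin genes 7 were lower and 1 higher, 9 and 1 adjusted over the list alone (median -0.241; adjusted p = 1.61e-07, and adjusted p = 0.188 with an estimated correlation). Against mock at 6 wk the myelin list did not pass in CAC (median -0.0663; adjusted p = 0.326), and it was higher in NCAC (median 0.239; 5 of 16 adjusted over the list alone; adjusted p = 1.76e-09, and adjusted p = 0.181 with an estimated correlation). Markers of other tissue moved in these libraries too. The brainstem list was higher in NCAC than in mock at 6 wk (median 0.419; adjusted p = 0.0147, and adjusted p = 0.252 with an estimated correlation), with library means of 2.465 to 3.499 on the log2 scale in NCAC, 2.39 to 2.646 in mock and 2.565 to 3.692 in CAC. It lost its call without NCAC replicate 4 or 5 (adjusted p = 0.0594 or 0.0558) or with a mean TPM of at least 5 (0.102), and its median was 0.242 without NCAC replicate 5. Red blood cell (median -0.94) and choroid plexus genes (-0.41) were lower as lists in CAC than in NCAC at 6 wk (adjusted p = 0.00777 and 0.0152; with an estimated correlation adjusted p = 0.449 and 0.785). Both lost their call without CAC replicate 3 (adjusted p = 0.0626 and 0.0704) and with quantile normalization (0.0532 and 0.199). The choroid plexus list also lost it without CAC replicate 4 (adjusted p = 0.089), with median-of-ratios scaling (0.171), sample weights (0.139) or the covariate made from it (0.24), and without mitochondrially encoded genes (0.103). Of 10 inflammation genes 6 were higher in CAC than in NCAC at 6 wk, 8 adjusted over the list alone (adjusted p = 1.03e-06), but the list did not pass with an estimated correlation (adjusted p = 0.0789) or a mean TPM of at least 5 (adjusted p = 0.999). At 2 wk the glucocorticoid and immediate early lists were lower in CAC than in NCAC (median -0.348 and -0.336; adjusted p = 1.43e-05 each, and adjusted p = 0.594 and 0.59 with an estimated correlation), while choroid plexus genes were higher (median 0.62; adjusted p = 2.79e-04, and adjusted p = 0.668 with an estimated correlation).

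Of the genes called against mock and against NCAC at 8 wk, 1328 were in both, 888 higher and 440 lower, where independent lists would share 150 and 42.4; both comparisons use the same CAC libraries. At 6 wk 172 genes were in both. Comparisons of different weeks share no library: of 248 genes called against mock at 6 wk, 184 were also called at 8 wk, 154 higher and 30 lower, against 27.3 and 3.3 for independent lists. Fold changes of CAC and NCAC against the same mock libraries at 8 wk correlated across genes with r = 0.444, against a mean of 0.517 in simulated unchanged groups. Their covariance was 0.0133, against a mean of 0.00798 and a highest value of 0.0143 in 100 simulations; genes are not independent replicates. With the mock libraries split between the comparisons the median r was 0.123.

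The last question was whether the differences developed over time. Among the 2990 genes called at 8 wk, the log2 fold change had the same sign in 2104 at 2 wk (70.4%), 2652 at 4 wk (88.7%) and 2679 at 6 wk (89.6%). In 100 simulations of an earlier week without a difference, made from libraries outside this 8 wk comparison, the share had a median of 51.2% and ranged from 19.5 to 83.3%. The share at 2 wk lay within that range, and those at 4 and 6 wk lay above it. In a direct test of whether the CAC against mock difference changed between 2 and 8 wk, limma called 223 genes, 138 upward and 85 downward, a count that varied widely with the setting. Lrg1 (2.39), Map3k6 (2.18), Sult1a1 (2.02), Lcn2 (1.96) and Fkbp5 (1.91) changed most upward, and Fabp7 (-1.86), Sost (-1.54), Serpinb1a (-1.38), Dlk2 (-1.16) and the myelin gene Pllp (-0.86) most downward. The upward share of 61.9% was 52% with median-of-ratios scaling and 47.7% with quantile normalization, and without mitochondrially encoded genes 110 changed upward and 159 downward. Lrg1, Lcn2 and Serpinb1a kept this call in each alternative that tested them (adjusted p up to 0.00656, 0.0239 and 0.0395), whereas the other 7 lost it with a replicate block (0.104 to 0.155) and in a fit on these 4 groups alone (0.0535 to 0.0922). The count was 46 in that fit, 20 with a replicate block, 92 with no filter and 722 with sample weights, and ranged from 51 without CAC replicate 6 of 8 wk to 669 without CAC replicate 3 of 8 wk. It was 92 and 97 without CAC replicates 1 and 2 of 8 wk, 55 and 62 without mock replicates 1 and 3 of 8 wk, 58, 111, 91 and 105 without CAC replicates 1, 3, 4 and 5 of 2 wk, and 82, 112, 106 and 105 without mock replicates 1, 2, 4 and 5 of 2 wk. Between mock at 8 wk and mock at 2 wk limma called 0 genes, with 1211 at an unadjusted p under 0.05, and 2 and 1 without mock replicates 2 and 4 of 8 wk. As lists, microglial (median 0.313), interferon (0.356) and lymphocyte genes were higher in mock at 8 wk than in mock at 2 wk (adjusted p = 2.74e-12, 1.15e-07 and 2.34e-05; with an estimated correlation adjusted p = 0.163, 0.409 and 0.014). The microglial median was 0.186 without mock replicate 5 of 8 wk. The interferon median was 0.218 and 0.551 without mock replicates 3 and 4 of 8 wk, and 0.589 without mock replicate 5 of 2 wk. The lymphocyte list had a median of 0.448 without mock replicate 5 of 8 wk and 0.189 with no filter. The replicate block was built within each week, so it cannot test a difference between mock of 2 weeks. In the change from 2 to 8 wk it also takes out CAC replicates 6 and 7 of 8 wk, whose numbers no other library has.

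On build mm10, Lrg1 lies on chromosome 17 from 56119678 to 56122001 and Plin4 on the same chromosome from 56100591 to 56109803. Fkbp5 lies on chromosome 17 from 28399094 to 28517527, Fabp7 on chromosome 10 from 57784881 to 57788450, Opalin on chromosome 19 from 41061710 to 41077113 and Lcn2 on chromosome 2 from 32384633 to 32388252. All 6 are annotated as protein-coding, and the levels are sums over whole genes.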

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

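The tests of a response to any tumour, of a single mock library, of blood, of reads shared between copies and of alleles were chosen only after the results were seen, as were the covariate sets of Per3 alone and of the clock genes without Per3, and the immediate early covariate in CAC against NCAC.

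Of 95 sets of libraries, 14 held a library far from the others of its group, where about 4.75 are expected by chance. CAC replicate 3 of 8 wk was the far library in 5 of the reported levels: Etnppl was lowest at 9.99 TPM (others 58.3 to 91.5), and Lcn2 at 12.9 (others up to 5.88), Fabp7 at 77.1 (up to 31.3), Tnc at 14.2 (up to 5.82) and Sost at 6.1 TPM (up to 1.95) were highest. Its glucocorticoid list mean was 4.955 on the log2 scale, against 5.7 to 6.294 in the other CAC libraries of 8 wk and 4.103 to 4.839 in mock. Its Hbb-bs, a haemoglobin transcript, stood at 7710 TPM against at most 1050 in the other 6 CAC libraries of 8 wk. Mock replicate 5 of 8 wk was highest for Plin4 (5.67 TPM), Lrg1 (2.8) and Igkc (426, against at most 10.6). Mock replicate 2 of 8 wk had the highest Tnc (24.9 TPM) and the lowest mitochondrial share (18.9%). Hbb-bs was highest in mock replicate 5 of 2 wk (1520 TPM), Gkn3 lowest in mock replicate 1 of 6 wk (5.65 TPM), and mock replicate 1 of 4 wk had the fewest symbols above 0 (18300).

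By a test of the difference itself, limma called 223 genes as changed between 2 and 8 wk in CAC against mock, with Lrg1 at 2.39, Map3k6 at 2.18, Sult1a1 at 2.02, Lcn2 at 1.96 and Fkbp5 at 1.91, and with Fabp7 at -1.86, Sost at -1.54, Serpinb1a at -1.38, Dlk2 at -1.16 and Pllp at -0.86 on the log2 scale. This count was 20 with a replicate block, 46 in a fit on the 4 groups alone, 92 with no filter and 722 with sample weights, and another split of the libraries gave 299. Lrg1, Lcn2 and Serpinb1a kept the call in each alternative that tested them, and the other 7 lost it with the block and in the fit on the 4 groups alone.

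The rise of glucocorticoid genes in CAC at 8 wk may reflect the cachectic tumour, or how and when tissue was taken. A response of the same size to any tumour is argued against as the whole cause at 8 wk. There 18 of 20 genes were also higher in CAC than in NCAC (median log2 fold change 1.33, list adjusted p = 0.0911 with an estimated correlation). The median of NCAC against mock was, however, 0.172 at 8 wk and 0.448 at 2 wk. Tumour size was not available here, so a response that grows with the tumour cannot be told apart. Handling stress that raises immediate early genes goes with their higher list in CAC than in NCAC at 8 wk (median 0.536, list adjusted p = 0.0245, and 0.599 with an estimated correlation). That call was lost without CAC replicate 2 or 7 or NCAC replicate 2 or 3. For the difference from NCAC such stress was tested only as far as the immediate early mean recorded it at collection. With that mean as a covariate the glucocorticoid median against NCAC was 1.1 in place of 1.33, so little of the difference followed the mean. Against mock the glucocorticoid median was 1.5 in place of 1.54. This cannot decide, since the immediate early list did not pass against mock (median 0.234, list adjusted p = 0.735), so its mean could hardly move the result. Handling stress that leaves these genes unchanged, or no longer changed at collection, was not tested. A different hour of collection cannot be told apart: with Arntl, Nr1d1, Dbp and Per3 as covariates the median was 0.544 and the list passed (adjusted p = 3.39e-09), but only 2 of 20 members and 87 genes were called. Per3 keeps it open, since it was itself called higher in CAC, and the median was 1.13 without Per3 and 0.759 with Per3 alone.

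Immunoglobulin and MHC class II genes were lower in CAC than in mock at 8 wk, with 8 of 12 genes called. Their calls rested on mock replicate 5: without it 0 of the 8 were called by limma, with adjusted p-values from 0.0572 to 0.699 for these 8. Blood carried over into that library is argued against, since its Hbb-bs was 337 TPM and that of the other mock libraries of 8 wk was 392 to 753. Immune cells or another tissue in that sample, and a difference of that animal, stay open and were not tested.

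Rps26, a ribosomal protein gene (mm10 chromosome 10 from 128624534 to 128626747), and its pseudogene Rps26-ps1 (chromosome 8 from 107439131 to 107439579) stood at separate levels between libraries. The pseudogene's share of the sum of both was under 0.1 in 44 libraries of all 12 groups, 0.3 to 0.7 in 14 libraries of 8 groups, over 0.9 in 4 libraries of 3 groups, and in between in 0. Sharing of reads in the same way in every animal is argued against by the range of that share, which was 1, and a batch by rank correlations with other such loci of at most 0.372 in size. Alleles that differ between animals are a candidate explanation, since the sum of both varied by 8.37% (CV), against 37% for Rps26 and 170% for the pseudogene. If alleles are the cause, animals of the same group differed in genotype, which argues against 1 inbred strain such as C57BL6/J. No sequence was examined, so the labels' disagreement on the strain is not settled.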

How the results depend on the processing

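Of the alternatives, removing mitochondrially encoded genes, removing genes with separate levels and leaving out 2 libraries of 8 wk together were chosen after seeing the data. The leading genes of CAC against mock at 8 wk kept their direction and call in each alternative that tested them: Lrg1 in 23 (log2 fold change 2.44 to 2.97; adjusted p up to 2.98e-04), Lcn2 in 23 (1.8 to 3.23), Fkbp5 in 24 (1.86 to 2.42), Plin4 in 24 (2.36 to 3.37; adjusted p up to 0.0142), Fabp7 in 24 (-2.38 to -1.8) and Opalin in 24 (-1.66 to -1.26). The fit with clock gene covariates was not among these alternatives. It called 87 genes and 2 of 20 glucocorticoid list members, so not all of Lcn2, Fkbp5 and Plin4, which are members, kept their call there. Counts are limma's, and where a setting moved one, the cause was not tested unless stated. Depth is unknown, so what it limits cannot be given.

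With the 2 compared groups fitted alone, CAC against mock gave 0 genes at 4 wk (955 at an unadjusted p under 0.05), 0 at 6 wk (2057) and 1648 at 8 wk, CAC against NCAC gave 0 at 4 wk (1041), 348 at 6 wk and 685 at 8 wk, and the change from 2 to 8 wk gave 46. The fits on 2 groups had 8 or 10 residual degrees of freedom in place of 50, and the change from 2 to 8 wk was fitted on its 4 groups. Sample weights gave 0 genes in CAC against mock at 4 wk, 629 at 6 wk, 5 in NCAC against mock at 2 wk, 1, 0, 2624 and 2630 in CAC against NCAC at 2, 4, 6 and 8 wk, 722 for the change from 2 to 8 wk and 58 for mock over time.

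Replicate numbers did not pair the libraries: of 60 pairs of the same number 16 had r over 0.1 (-0.239 to 0.396), and 16 of 62 libraries correlated best with their own number. With a replicate block CAC against mock gave 158 genes at 6 wk and 1894 at 8 wk, and NCAC against mock gave 0 at 2 wk. CAC against NCAC gave 0 at 4 wk and 682 at 8 wk, and the change from 2 to 8 wk gave 20. CAC replicates 6 and 7 of 8 wk share their number with no other library. The block therefore takes them out of the comparisons of 8 wk, so lower counts there partly reflect fewer libraries.

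The limit of 1.5-fold left 58 and 241 genes in CAC against mock at 6 and 8 wk, 96 and 167 in CAC against NCAC, 0 in NCAC against mock at 2 wk and 78 for the change from 2 to 8 wk. A pseudocount of 0.1 gave 2 genes for mock over time. No filter gave 3 genes in CAC against mock and 2 in CAC against NCAC at 4 wk, 92 for the change from 2 to 8 wk and 5 for mock over time. A mean TPM of at least 5, under which Lrg1 is not tested, gave 0 and 0 genes at 4 wk and 2 for mock over time. The choroid plexus covariate gave 0 genes in CAC against mock at 4 wk.

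Median-of-ratios scaling gave 0 genes in CAC against mock and 0 in CAC against NCAC at 4 wk, 1 in NCAC against mock and 1 in CAC against NCAC at 2 wk, and 2 for mock over time. Quantile normalization gave 0 and 2 at 4 wk, 1 and 1 at 2 wk, and 3 for mock over time. The farthest that either scaling moved the median log2 fold change of all genes was -0.0409, in CAC against NCAC at 6 wk with quantile normalization. Without mitochondrially encoded genes NCAC against mock gave 0 genes at 2 wk, CAC against NCAC 2 at 4 wk and mock over time 2. Without CAC replicate 3 and mock replicate 5 of 8 wk the change from 2 to 8 wk gave 798 genes, CAC against mock at 8 wk 3289, CAC against NCAC 2301 and NCAC against mock 0. An estimated correlation left 1 of 14 lists in CAC against mock at 8 wk.

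With each replicate left out in turn, CAC against mock gave 0 to 0 genes at 2 wk, 0 to 4 at 4 wk, 20 (without CAC replicate 1) to 527 (without CAC replicate 4) at 6 wk and 2120 (without mock replicate 3) to 3521 (without CAC replicate 3) at 8 wk. CAC against NCAC gave 0 to 0, 0 to 10, 247 to 1690 and 1101 to 2304, and NCAC against mock 0 to 2 at 2 wk and 0 to 0 at 4, 6 and 8 wk. The change from 2 to 8 wk gave 51 to 669, mock over time 0 to 2, and 13 to 14 lists passed in CAC against mock at 8 wk. Over these fits 747 of the calls of named genes were lost and 3335 held, as were 261 and 1599 of those of lists.

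Directions turned in 14 cases. Under quantile normalization, which fixes the highest ranks by construction, mt-Nd4 (0.0143), mt-Nd4l (0.0235) and mt-Cytb (0.0359) in CAC against mock at 8 wk and mt-Nd4 (0.02) in CAC against NCAC at 6 wk changed sign, and the mitochondrially encoded list had a median of 0 in CAC against mock at 6 wk, in CAC against NCAC at 6 wk and in the change from 2 to 8 wk. A mean TPM of at least 5 turned the inflammation list in CAC against NCAC at 4 wk (0.0318; fewer members tested), and sample weights the glucocorticoid list in CAC against mock at 4 wk (0.00364). The choroid plexus covariate, made from that list, turned the choroid plexus list at 2 wk in CAC against mock (6.52e-04), NCAC against mock (0.0369) and CAC against NCAC (-0.0229). With each replicate left out, the meningeal list in CAC against NCAC at 2 wk lay between -0.0277 (without NCAC replicate 3) and 0.191 (without NCAC replicate 2), and the ribosomal list in NCAC against mock at 8 wk between 0.00228 (without mock replicate 2) and 0.0302 (without mock replicate 3). Values are log2 medians or fold changes; the sign of a list is that of its test.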

Other observations

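Genes of vessels and matrix changed both ways in CAC against mock at 8 wk. Of 16 endothelial genes 6 rose and 4 fell, of 13 basement membrane genes 3 rose and 2 fell, and of 16 meningeal and collagen genes 2 rose and 1 fell; these lists did not pass (adjusted p = 0.735, 0.735 and 0.926). Mgp, a matrix protein that limits calcification, had a log2 fold change of 1.10, Sparc 0.75 and Fmod 0.73, whereas Kdr, a receptor for vascular growth factor, was at -0.69, Lum at -0.61 and Nid1 at -0.35. Of 15 fasting genes 3 rose and 1 fell, and of 17 atrophy and autophagy genes 6 rose and 2 fell (adjusted p = 0.693 and 0.201). Pdk4 (1.32), Angptl4 (0.65), which inhibits lipoprotein lipase, Ucp2 (0.52), Foxo1 (0.89), Foxo3 (0.19) and Map1lc3b (0.17) rose, while Fbxo32, a ubiquitin ligase of muscle atrophy, was at -0.38 and Slc16a1, a monocarboxylate transporter, at -0.28. Against NCAC at 8 wk 3 of 16 immediate early genes were higher in CAC, Klf4 (1.14), Junb (0.70) and Btg2 (0.50), with an adjusted p of 0.0245 for the list and an adjusted p of 0.599 with an estimated correlation. The call of this list was lost without CAC replicate 2 (adjusted p = 0.0868) or 7 (0.0981) or NCAC replicate 2 (0.1) or 3 (0.147). The complement genes C1qc (0.53) and C1qb (0.51) were also higher.

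The Purkinje, granule and inhibitory lists did not pass in CAC against mock at 8 wk. Of 12 Purkinje genes 1 fell (Car8, -0.17), of 12 granule genes 1 fell (Slc17a7, -0.15) and 1 rose (Reln, 0.18), and of 12 inhibitory genes 3 rose (Lgi2 0.42, Pvalb 0.14 and Prkcd 0.27). The call of Pvalb was lost under quantile normalization, with a log2 fold change of 0.01 (adjusted p = 0.915), and in a fit on the 2 groups alone (adjusted p = 0.0535); its adjusted p ranged from 5.6e-05 to 0.915 over the alternatives. At 6 wk the Purkinje and granule lists were lower with the preset correlation (median -0.0741 and -0.0723; adjusted p = 2.18e-06 and 0.00532), not with an estimated one (adjusted p = 0.424 each). In limma 0 members of either were called over all genes, with 5 and 3 of 12 at an unadjusted p under 0.05, and 4 and 1 were lower adjusted over the list alone. Over all 34 lists, 11, 8, 13 and 14 passed at 2, 4, 6 and 8 wk in CAC against mock with the preset correlation. In NCAC against mock, with at most 2 genes called, 14, 5, 15 and 8 passed, and 12 passed for mock over time. The number of lists that pass with the preset correlation thus does not set CAC apart. With an estimated correlation the inflammation list passed in CAC against mock at 6 and 8 wk, and the lowest adjusted p was 0.444 at 2 wk and 0.151 at 4 wk. In NCAC against mock 2, 0, 0 and 2 lists passed with it.

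Other splits of the compared libraries were drawn 100 times per comparison, the real one included. In CAC against mock at 8 wk 1 of 100 splits, the real one with 2990 genes, reached that count, and the highest other gave 2243. The real split likewise gave the most genes at 6 wk (1 of 100, 248 against 119), and for CAC against NCAC at 6 wk (1 of 100, 1361 against 780) and 8 wk (1 of 100, 1695 against 1571). With 100 splits the share cannot fall under 1 of 100, and each split used the spread shared by all 12 groups. A fit of CAC and mock at 6 wk alone called 0 genes. The share of splits that reached the real count was also under 0.05 for the change from 2 to 8 wk (2 of 100, 223, with 299 in the highest other) and for NCAC against mock at 2 wk (4 of 100, 2, with 150). In both another split called more genes than the real one. Chance could not be excluded at 4 wk for CAC against mock (6 of 100; 1, with 178) or against NCAC (6 of 100; 1, with 95). Where limma called 0 genes, 100 of 100 splits gave at least as many by construction, so that share tests nothing. These were CAC against mock at 2 wk (697 at an unadjusted p under 0.05, highest other 1) and NCAC against mock at 4, 6 and 8 wk (306, 1202 and 1038, highest other 20, 1 and 7). CAC against NCAC at 2 wk (987, highest other 3) and mock over time (1211, highest other 4) were the rest. Splits that called many times the real count, at 4 wk and in NCAC against mock at 2 wk, point to a structure of these samples, and what it is was not tested.

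Whether animals with more glucocorticoid response also differ in other lists was tested within groups, as a hypothesis, on scores with their group means removed and without genes shared by the lists (62 libraries, 4 relations, two-sided permutation tests within groups, 100000 resamples). The cholesterol synthesis score was lower where the glucocorticoid score was higher: Pearson's r was -0.647 (p = 1e-05, the smallest that the permutations can give; adjusted p = 4e-05) and Spearman's rho -0.603 (adjusted p = 4e-05). Without the 2 libraries farthest from the median, CAC replicate 3 of 8 wk and CAC replicate 2 of 4 wk, r was -0.575. It was -0.443 in the 40 mock and NCAC libraries, and -0.525, -0.802, -0.406 and -0.767 at 2, 4, 6 and 8 wk. The myelin score had r = -0.495 (p = 0.00038; adjusted p = 0.000507) and rho = -0.4 (p = 0.00784; adjusted p = 0.0157), with r = -0.397 without those 2 libraries and -0.292 in mock and NCAC, but -0.0163 at 2 wk against -0.675, -0.407 and -0.543 at 4, 6 and 8 wk. The inflammation score had r = 0.544 (p = 0.00011; adjusted p = 0.00022) but rho = 0.276 (p = 0.0474; adjusted p = 0.0632), with r = 0.484 without those 2 libraries, 0.158 in mock and NCAC, and 0.471, 0.632, 0.554 and 0.53 by week; the rank correlation did not pass. For the precursor score r was -0.23 (p = 0.162; adjusted p = 0.162) and rho -0.0338 (adjusted p = 0.83), with r = -0.101 without those 2 libraries, 0.0597 in mock and NCAC, and 0.368, -0.161, -0.3 and -0.616 by week. The bound set for it in advance read an adjusted p of 0.05 or more as evidence against a relation; that bound was wrong, since a p that misses the threshold does not exclude one, and it was dropped after the result was seen, so this relation stays open. Cholesterol synthesis genes may thus vary with the glucocorticoid genes between animals of 1 group; no batch is given in the labels within which this could be repeated, and the order of events was not tested.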
